A study of Mus musculus with 6 samples.

How the data were processed

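The series measured polyadenylated transcripts in primary neural stem cells taken from mouse embryos at day 13.5 and grown as neurospheres, floating clusters of dividing progenitors. Medium held 20 ng/ml of epidermal growth factor and 20 ng/ml of fibroblast growth factor 2, with 20% oxygen. Neurospheres were lysed on day 4 after dissociation. There were 3 WT libraries and 3 libraries from cells without Pml, the gene of the promyelocytic leukemia protein, which builds nuclear bodies. Per the labels' protocols, RNA with an integrity number above 7 went into a 3′ tag library kit (QuantSeq forward), with 20 to 24 PCR cycles, and was sequenced on a NextSeq. All 6 libraries carry the same batch date in the labels. The labels number the replicates but do not say whether they came from separate cultures or embryos. All p-values therefore measure the spread between these 6 samples, which may be technical.

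Per the submitters' processing notes, the authors used FastQC, HISAT2, HTSeq, edgeR and the mm10 genome build; their versions, the gene annotation and the strand setting are not given in the sources used here. The deposited table holds whole-number read counts per gene, not normalized, for 24421 gene symbols, and 8329 of these had 0 counts in every library. It also holds the authors' own comparison: a log2 fold change, a p-value and an adjusted p-value per gene, per the file headers. The authors' p-values cover 12349 genes, exactly those above 1 CPM (count scaled to library total) in at least 3 libraries. The deposited log2 fold changes and p-values were used only for the comparison named as theirs. Library columns were matched to samples by the library names in the labels. Per-sample columns left unused numbered 0.

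Total counts ran from 1775152 to 5917505 per library. A 3′ tag protocol places reads near the transcript end, so counts do not scale with transcript length. They do depend on where the annotated end lies. Without a stated strand setting, reads of overlapping or antisense genes cannot be told apart. Genes with near-identical copies, such as ribosomal protein genes with processed pseudogenes and clustered histone genes, are uncertain. The reads carried no molecular identifiers that are named in the sources, so intervals cover counting error only; they are exact Clopper-Pearson intervals at the 95% level.

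Counts were analysed in R 4.3.3 with edgeR 4.0.16 and limma 3.58.1. Genes were kept by edgeR's default filter (a count minimum of 10 and a total of 15), which left 11317, and library factors came from the trimmed mean of M values. The main test was edgeR's robust quasi-likelihood F test of Pml knockout against WT with no covariate. Genes passed at a Benjamini-Hochberg adjusted p under 0.05. The standard error of a log2 fold change was its size divided by the square root of F. Levels are CPM with the library factors, as mean ± SD over 3 libraries.

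Before the data were examined, 38 gene lists were fixed from general knowledge, covering cell identity, other cell types, mitochondria, stress responses, cell cycle, metabolism and signalling. The 31 with at least 5 tested members were tested with limma's camera on log2 CPM (prior count 2) with a preset inter-gene correlation of 0.01. Camera asks whether a list moved relative to the other genes. It was repeated with a correlation estimated per list, and with limma's fry, which asks whether the members move on balance, or in either direction, without comparing them with other genes. The number of members past the threshold when adjusted over the list alone was also taken.

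The rule for named genes, fixed at the same time, took Pml in every library. It took up to 12 of the largest rises and 12 of the largest falls past the threshold, with at least 5 CPM on average and no overlap between groups. It also took the 5 smallest p-values in each direction and up to 4 members per list with the smallest p. Not all members so chosen are printed; for each list the text gives those with the smallest p, except 1 gene that is not reported here.

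Alternatives planned before the data were examined were 3 other normalizations, 2 other count filters, DESeq2 1.42.0, limma voom, edgeR's exact test and a non-robust fit. They also covered an adjusted p of 0.01, a 1.5-fold minimum, the replicate number as a block, and each library left out in turn. After the data were seen, 5 more were added: leaving out the 45S pre-ribosomal RNA row (Rn45s), leaving out a hepatocyte list of 69 genes, voom with library quality weights, leaving out WT replicates 1 and 2 together, and removing each library's trend with transcript length and GC content. Transcript features came from the GENCODE M21 annotation of GRCm38, the assembly that mm10 names, and coordinates are from it.

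The test was first tested on simulated data with the real means, library sizes and dispersions. Of 50 genes raised 4-fold, 88% were recovered, and of 50 lowered 4-fold, 70%, with 11085 genes tested. For 2-fold changes the share was 4% in each direction. In these runs 1 unchanged gene was called. The simulated dispersions set this limit: at 0.25 of them, 74% of the genes raised 2-fold and 66% of those lowered were recovered among 11149 genes, with 16 unchanged genes called. The simulation drew genes independently and gave both genotypes the same dispersions, with no shift of whole libraries. The shares recovered therefore need not hold for the real libraries. Figures were drawn with matplotlib 3.10.9.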

Results

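Gene expression was compared between Pml knockout and WT embryonic neural stem cells kept as neurospheres, with 3 libraries per genotype. The question set by the series title is how loss of Pml affects the way these cells differentiate, withstand stress and keep their mitochondria intact. WT replicates 1, 2 and 3 held 4413318, 1775152 and 3934519 counts. Knockout replicates 1, 2 and 3 held 5917505, 4980638 and 5596862. The 45S pre-ribosomal RNA row, Rn45s, took 41.9% of the counts in WT replicate 1 (95% interval 41.8 to 41.9) and 39.8% in WT replicate 2 (39.7 to 39.9). It took 19.6% in WT replicate 3 (19.6 to 19.7), and 17.6% (17.5 to 17.6), 14.6% (14.6 to 14.7) and 16.6% (16.6 to 16.6) in knockout replicates 1 to 3. Transcripts typical of hepatocytes, summed over a list of 69 genes written after the values were seen, made up 1700, 2655 and 567 CPM of the counts outside Rn45s in WT replicates 1, 2 and 3. In the knockout libraries they made up 346, 280 and 296.

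**Figure D1:**
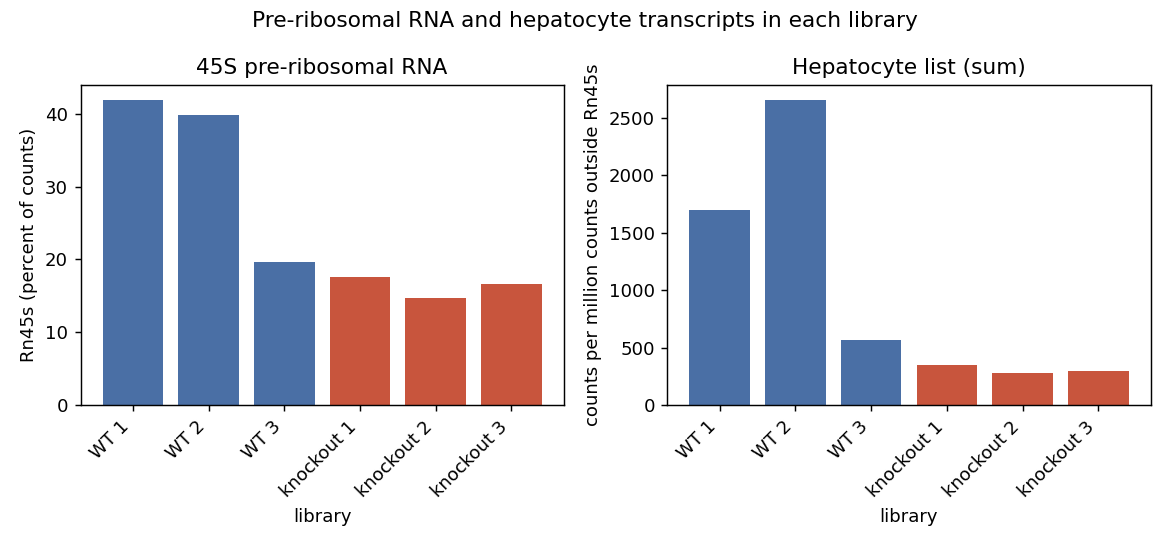
Bars give, for each library, the percent of counts from Rn45s (left) and the summed hepatocyte list in CPM of the counts outside Rn45s (right), with WT in blue and Pml knockout in red. WT replicates 1 and 2 stand at 41.9% and 39.8% Rn45s, and the other 4 libraries between 14.6% and 19.6%.

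The WT libraries differed more from each other than the knockout libraries did. Spearman correlations between pairs of WT libraries across genes were 0.874, 0.915 and 0.789. Those between knockout pairs lay between 0.963 and 0.975. WT replicate 3 correlated with knockout replicates 1 and 3 at 0.956 and 0.953, above its values with the other WT libraries. The main axis of a principal component analysis, 62.8% of the variance, set WT replicate 2 at -116 against 30.8 for WT replicate 3 and between 27.3 and 39.3 for the knockout libraries. No pair of libraries agreed within sampling noise.

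Pml itself (ENSMUSG00000036986.16, chromosome 9, 58218076 to 58249786, minus strand, GRCm38) had 36, 35 and 44 reads in WT replicates 1, 2 and 3. It had 14, 23 and 5 in the knockout libraries. That is 16.2 ± 10.2 CPM against 2.22 ± 1.53 (SD, n = 3 each), with no overlap between genotypes. Its log2 fold change of -2.81 (SE 0.661) had an unadjusted p of 0.00165 by edgeR and an adjusted p of 0.197, so it did not pass. It passed by DESeq2 (adjusted p 0.00524), by the edgeR exact test (0.00624), by voom with quality weights (0.00877) and without WT replicate 3 (0.0221). The quality weights favoured WT replicate 1 (1.62) over WT replicates 2 and 3 (0.392 and 0.353). Both that fit and the one without WT replicate 3 lean on WT libraries with high Rn45s shares. The labels do not state which part of the gene was removed, and a 3′ tag outside that part would not report on the deletion.

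Wdfy1 was the gene that rose in Pml knockout cells. It encodes a FYVE- and WD40-domain protein of early endosomes (ENSMUSG00000073643.11, chromosome 1, 79702262 to 79776143, minus strand, GRCm38). Reads numbered 16, 9 and 37 in the WT libraries and 346, 324 and 348 in the knockout libraries. The level went from 6.79 ± 1.85 to 52.5 ± 0.838 CPM (SD, n = 3 each), 7.71-fold, with a log2 fold change of 2.95 (SE 0.336) and an edgeR adjusted p of 0.0498. The pass was narrow by edgeR's quasi-likelihood test and depended on the setting. The adjusted p was 6.27e-11 by DESeq2, 1.30e-10 by the edgeR exact test, 0.00172 with no count filter and 0.00228 by voom with quality weights. It was 0.0448 with upper quartile factors, 0.0449 with a non-robust fit and 0.0479 without the hepatocyte list. It was 0.0105 without WT replicate 2, 0.00321 without WT replicate 3 and 0.000487 without both WT replicates 1 and 2. It rose to 0.0562 with DESeq2's size factors, 0.165 with library totals, 0.0581 with a minimum of 5 CPM, 0.0941 by voom, 0.0935 by glmTreat, 0.0502 without the Rn45s row and 0.0888 with transcript length and GC trends removed. It also rose, to 0.447, without WT replicate 1 and to 0.413, 0.648 and 0.545 without knockout replicates 1, 2 and 3. The fold change stayed between 2.56 and 3.34 on the log2 scale over the alternatives that give one.

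**Figure D2:**
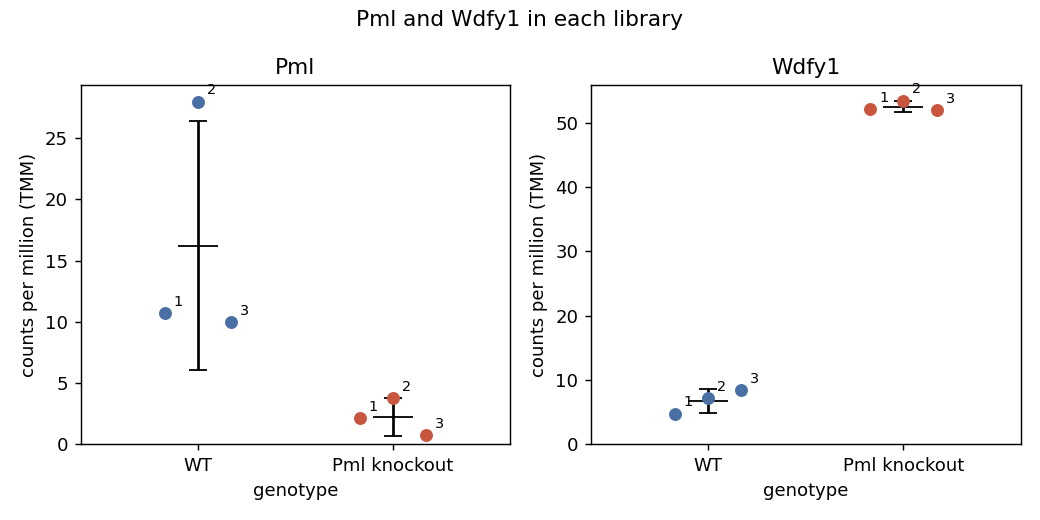
Points are CPM (with library factors) of Pml (left) and Wdfy1 (right) in each of the 3 WT and 3 Pml knockout libraries, numbered by replicate, with the mean and SD as bars. Pml averages 16.2 CPM in WT and 2.22 in the knockout, and Wdfy1 6.79 and 52.5.

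Among 11317 tested genes, 1 passed higher in the knockout and 0 passed lower by edgeR's quasi-likelihood test. At an unadjusted p under 0.05 there were 1798 genes, of which 758 were higher and 1040 lower, against 566 by chance. The groups did not overlap for 23.6% of genes, where chance gives 10%. Genes do not vary independently of each other, and these counts were not taken for other groupings of the libraries. The excess over chance therefore cannot be read as an effect of genotype. DESeq2 called 93 higher and 221 lower, the edgeR exact test 148 and 211, and limma voom 0 and 0. Leaving out WT replicate 3 gave 589 higher and 937 lower. Only the WT libraries with the higher Rn45s and hepatocyte shares stay in that fit. Its counts therefore cannot tell an effect of genotype from what sets those libraries apart from WT replicate 3. With all libraries the common biological coefficient of variation was 35.0%.

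The genes with the next smallest p on the higher side did not pass. Nr2f2, an orphan nuclear receptor of caudal forebrain progenitors, had 11.1 ± 3.54 CPM in WT and 42.4 ± 7.50 in the knockout (log2 fold change 1.91, SE 0.346). Ncoa1, a nuclear receptor coactivator, had a log2 fold change of 1.74 (SE 0.324). Lgmn, the lysosomal protease legumain, stood at 2.00 (SE 0.383). Vldlr, a reelin receptor, stood at 1.39 (SE 0.268). All 4 had an edgeR adjusted p of 0.197. On the lower side, Chaf1b, a subunit of the chromatin assembly factor that works at replication forks, had 25.7 ± 2.21 CPM in WT and 6.55 ± 1.27 in the knockout (log2 fold change -1.97, SE 0.342). Hist1h2ab, a histone H2A gene with near-identical copies, stood at -3.09 (SE 0.530). The other 3 were secreted plasma proteins made mainly by the liver: Mug1 at -2.90 (SE 0.513), Serpinc1 at -2.93 (SE 0.539) and Itih3 at -3.11 (SE 0.571). These 5 also had an adjusted p of 0.197. In WT replicates 1, 2 and 3, Itih3 had 280, 164 and 93 reads, and 68, 53 and 52 in the knockout libraries.

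Of the 31 gene lists tested, camera called 9 higher and 4 lower in the knockout. With a correlation estimated per list it called 0, with 0.480 as the smallest adjusted p. Fry called 0 for movement one way and 5 for change in either direction. Only the calls with the preset correlation therefore carry the lists below, and none of their members passed over all genes. WT replicates 1 and 2, with their higher Rn45s and hepatocyte shares, enter each of these comparisons on the WT side. Several lists called higher share members, so their calls are not independent. Gli3 is on the stem cell, dorsal and Hedgehog lists, and Id1 on the stem cell and BMP lists. Setting WT replicates 1 and 3 and knockout replicate 3 against the remaining libraries gave 12 called lists, beside 13 for the real grouping. The number of called lists therefore cannot be read as an effect of genotype.

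**Figure D3:**
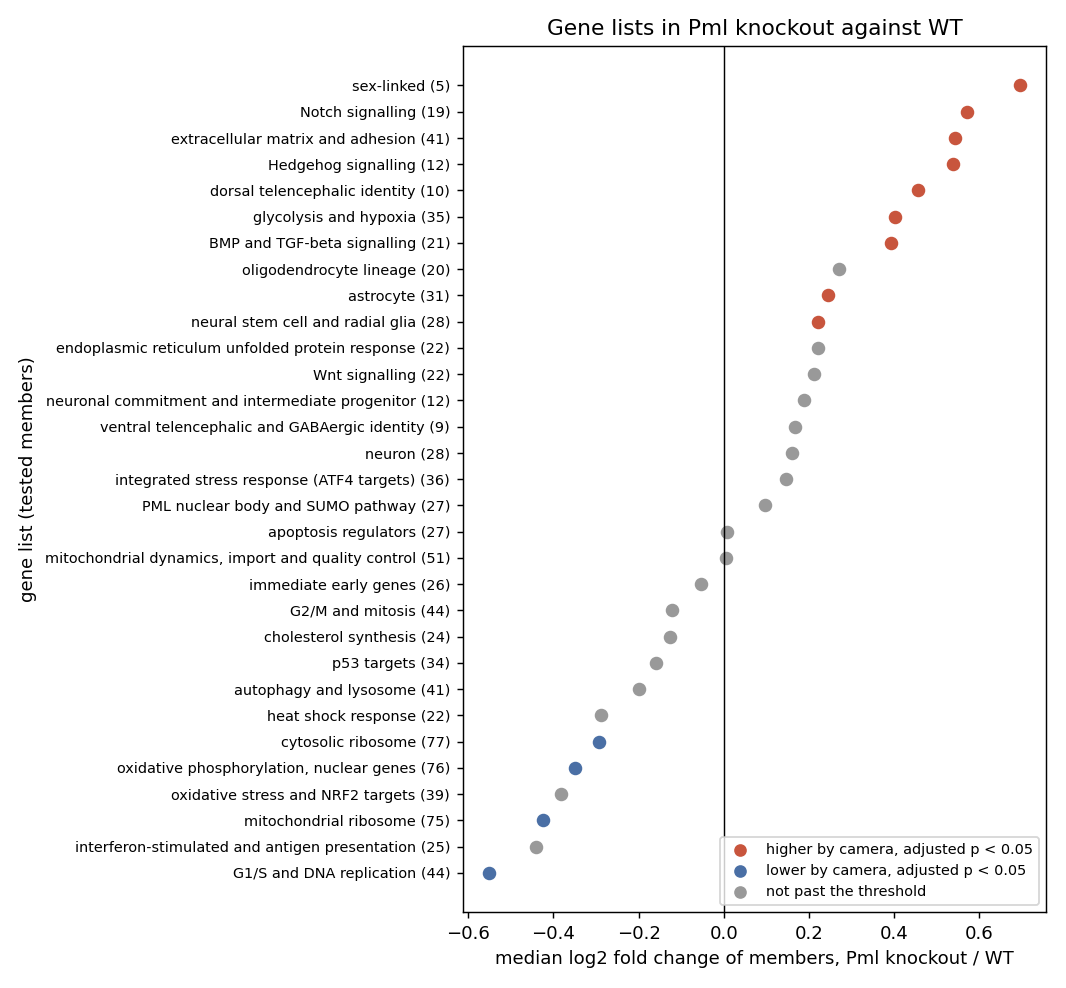
Each point is the median log2 fold change (Pml knockout over WT) of the tested members of a gene list, with the number of tested members in brackets; red and blue mark lists called higher and lower by camera with the preset correlation. Medians run from -0.55 for DNA replication to 0.70 for the sex-linked list.

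Extracellular matrix and adhesion genes were higher in the knockout. Of 41 tested members, 32 were higher and 9 lower, with a median log2 fold change of 0.54. The camera adjusted p was 0.000861, and the adjusted p = 0.480 with an estimated correlation. The mean of the list relative to each gene's average was -0.31, -0.33 and -0.34 (log2) in the WT libraries and 0.23, 0.46 and 0.28 in the knockout libraries. Loxl2, a lysyl oxidase that cross-links collagen, had 12.5 ± 3.93 CPM in WT and 36.7 ± 9.91 in the knockout. Col4a6, a basement membrane collagen chain, had 1.32 ± 0.495 and 6.53 ± 1.08. Mmp14, a membrane-bound metalloproteinase, had 42.6 ± 8.53 and 97.4 ± 29.7. No member passed over all genes or when adjusted over the list alone (0 and 0 by edgeR, 11 at an unadjusted p under 0.05). Without WT replicate 3 the list's adjusted p was 0.0894, although its mean relative change did not shrink (0.55 with all libraries, 0.61 without it).

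Genes of glycolysis and the hypoxia response were also higher, 25 of 35 tested, with a median log2 fold change of 0.40. The camera adjusted p was 0.0140, and the adjusted p = 0.748 with an estimated correlation. Pdk1, a kinase that inhibits pyruvate dehydrogenase, had 64.5 ± 18.5 CPM in WT and 139 ± 21.5 in the knockout. Ankrd37, a hypoxia-induced gene, had 6.33 ± 3.51 and 17.7 ± 0.370. By edgeR 0 members passed over all genes and 0 when adjusted over the list alone, and 11 were higher at an unadjusted p under 0.05. The list's mean in WT replicate 3 was -0.99 (log2), while WT replicates 1 and 2 stood at -0.03 and 0.33. The call ended without WT replicate 3 (adjusted p 0.785) and without knockout replicate 1 (0.239), where the mean relative change fell from 0.37 to 0.03 and 0.12. The mean rose to 0.67 without WT replicate 2 (2.49e-06), 0.56 without knockout replicate 3 (0.000169) and 1.13 without both WT replicates 1 and 2 (4.60e-12).

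The neural stem cell, dorsal telencephalic and astrocyte lists were higher in the knockout. Of 28 neural stem cell and radial glia genes, 20 were higher (median log2 fold change 0.22, camera adjusted p 0.0470, and adjusted p = 0.627 with an estimated correlation). Nr2e1, the nuclear receptor Tlx of neural stem cells, had 8.70 ± 3.13 CPM in WT and 22.3 ± 2.57 in the knockout. Of 10 dorsal telencephalic genes, 9 were higher (median 0.46, camera adjusted p 0.0470, and adjusted p = 0.627 with an estimated correlation). They include Gli3, a transcription factor of the Hedgehog pathway (4.87 ± 1.13 against 11.4 ± 0.277 CPM), and Nfia, a gliogenic transcription factor (482 ± 117 against 701 ± 61.7 CPM). Of 31 astrocyte genes, 20 were higher (median 0.25, camera adjusted p 0.0470, and adjusted p = 0.748 with an estimated correlation). Aqp4, the astrocytic water channel, had 13.3 ± 4.06 and 58.5 ± 36.6 CPM, and Ncan, the proteoglycan neurocan, had 409 ± 32.3 and 853 ± 266. Itih3 is on the astrocyte list and was lower. Adjusted over the list alone, 2 astrocyte genes passed (1 higher, 1 lower) and 0 of the stem cell and dorsal genes, against 0 over all genes for each list. These calls depended on single libraries and on the setting. Without WT replicate 3 the adjusted p was 0.247 for the stem cell list, 0.153 for the dorsal list and 0.785 for the astrocyte list. Without WT replicate 1 it was 0.0625 for stem cell and 0.0689 for astrocyte genes, and without WT replicate 2 it was 0.135 for dorsal genes. Without knockout replicate 2 the stem cell and dorsal lists had 0.137 each and the astrocyte list 0.211. Without knockout replicate 1 the dorsal list had 0.0735, and without knockout replicate 3 the astrocyte list had 0.1002. The mean relative change of the astrocyte list, 0.20 with all libraries, was 0.06 without WT replicate 3 and 0.06 without knockout replicate 2. It rose to 0.66 without WT replicate 2 (adjusted p 4.23e-05), 0.37 without knockout replicate 1 (0.00269) and 1.17 without both WT replicates 1 and 2 (2.10e-07). That of the dorsal list fell from 0.47 to 0.28 without WT replicate 2 and was 0.53 without WT replicate 3, and that of the stem cell list stayed between 0.32 and 0.48 with single libraries left out. With the length and GC trends removed the stem cell list had 0.242, its mean relative change falling from 0.39 to 0.24, and the dorsal list 0.0666, with a mean of 0.39, while the astrocyte list had 0.0493. Without both WT replicates 1 and 2 the dorsal list had 0.314 and a mean of 0.06. With library totals the dorsal list had 0.0517 and the astrocyte list 0.0656, at means of 0.45 and 0.29.

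Signalling lists were higher for Notch, Hedgehog and BMP/TGF-beta. Of 19 Notch genes 14 were higher (median log2 fold change 0.57, camera adjusted p 0.0470, and adjusted p = 0.627 with an estimated correlation). Hey2, a transcriptional repressor induced by Notch, had 1, 0 and 0 reads in WT and 22, 30 and 25 in the knockout. Dll1, a Notch ligand also on the neuronal commitment list, had 6.16 ± 2.14 and 17.4 ± 3.15 CPM. Lfng, which modifies Notch receptors, went the other way with 156 ± 77.8 and 50.6 ± 2.09 CPM. Adjusted over the list alone 3 Notch genes passed, 2 of them higher, against 0 over all genes. Of 12 Hedgehog genes 9 were higher (median 0.54, camera adjusted p 0.0487, and adjusted p = 0.627 with an estimated correlation). They include Gli3 (above) and Hhip, which binds Hedgehog ligands (3.93 ± 1.73 against 8.85 ± 1.24 CPM). Of 21 BMP and TGF-beta genes 16 were higher (median 0.39, camera adjusted p 0.0470, and adjusted p = 0.627 with an estimated correlation). The receptor Bmpr1b had 20.7 ± 5.70 and 41.0 ± 14.5 CPM, and the target Id1 had 33.8 ± 9.19 and 65.8 ± 24.5. In the Hedgehog and BMP lists 0 members passed over all genes and 0 when adjusted over the list alone.

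Each of these signalling calls ended when single libraries were left out and under several other settings. For Notch the adjusted p was 0.0535 without WT replicate 2, 0.237 without WT replicate 3 and 0.133 without knockout replicate 2. For Hedgehog it was 0.0625, 0.248 and 0.145 without WT replicates 1, 2 and 3, and 0.157 without knockout replicate 1. For BMP and TGF-beta it was 0.160 and 0.277 without WT replicates 1 and 3, and 0.144 without knockout replicate 2. The mean relative change of Hedgehog fell from 0.52 to 0.29 without WT replicate 2 and was 0.69 without WT replicate 3. That of Notch was 0.50, and that of BMP and TGF-beta 0.36, without WT replicate 3, and BMP and TGF-beta rose to 0.70 without WT replicate 2 (adjusted p 0.000272) and 0.68 without both WT replicates 1 and 2 (0.00327). With the length and GC trends removed BMP and TGF-beta had 0.353, the mean relative change falling from 0.42 to 0.21, and Hedgehog 0.118, with a mean of 0.37, while Notch had 0.0493. With a minimum of 5 CPM Notch had 0.108, its mean falling from 0.56 to 0.35, Hedgehog 0.124 and BMP and TGF-beta 0.0628, at means of 0.47 and 0.41. Without both WT replicates 1 and 2 Hedgehog had 0.403 and a mean of 0.05. With library totals the Notch, Hedgehog and BMP lists had 0.0924, 0.108 and 0.0517, at means of 0.56, 0.47 and 0.45.

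The list of sex-linked genes, which holds Y-linked genes, was higher too, with 5 of 5 tested members higher (median log2 fold change 0.70). The camera adjusted p was 0.0470, and the adjusted p = 0.627 with an estimated correlation. Kdm5d had 30, 13 and 42 reads in WT and 147, 99 and 141 in the knockout libraries, and Ddx3y had 66, 37 and 126 against 275, 271 and 242. Both genotypes therefore held Y-linked reads in every library. Adjusted over the list alone 0 passed, and 0 over all genes, by edgeR, with 2 at an unadjusted p under 0.05. The adjusted p of the list was 0.0789 without WT replicate 1, 0.150 without WT replicate 3 and 0.117 without knockout replicate 2, with mean relative changes of 0.60, 0.76 and 0.61 against 0.66 with all libraries. It was 0.353 with the length and GC trends removed, where the mean fell to 0.36, and 0.247 without both WT replicates 1 and 2, where it fell to 0.26. With library totals it was 0.0603, at a mean of 0.64.

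Genes of the G1/S transition and DNA replication were lower in the knockout, 43 of 44 tested, with a median log2 fold change of -0.55. The camera adjusted p was 0.000384, and the adjusted p = 0.748 with an estimated correlation. Adjusted over the list alone 6 passed, all lower, against 0 over all genes. Chaf1b (above) was joined by Rfc2, a clamp loader subunit (89.0 ± 37.9 against 33.6 ± 6.14 CPM), and Mcm7, part of the replicative helicase (280 ± 30.5 against 134 ± 27.6 CPM). The mean of the list relative to each gene's average was 0.42, -0.70 and 0.85 (log2) in WT replicates 1, 2 and 3 and 0.04, -0.50 and -0.11 in the knockout libraries. Without WT replicate 3 the adjusted p was 0.429 and the mean relative change went from -0.56 to -0.28. It went to -0.88 without WT replicate 2 (adjusted p 1.04e-15) and to -1.21 without both WT replicates 1 and 2 (1.33e-19). The G2/M and mitosis list was not called (21 of 44 higher, camera adjusted p 0.545). Cdc20, an activator of the anaphase-promoting complex, had 171 ± 43.8 CPM in WT and 108 ± 22.2 in the knockout. That list's adjusted p was 0.000271 without WT replicate 2 and 3.16e-08 without both WT replicates 1 and 2.

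Nuclear genes of mitochondrial protein synthesis and respiration were lower on average, but the genotypes overlapped. Relative to each gene's average, the mitochondrial ribosomal list stood at 0.282, -0.095 and 0.213 (log2) in the WT libraries. It stood at -0.046, -0.323 and -0.031 in the knockout libraries. The oxidative phosphorylation list stood at 0.186, -0.058 and 0.137 against -0.089, -0.26 and 0.084. The cytosolic ribosomal list stood at 0.402, -0.11 and -0.05 against 0.108, -0.245 and -0.106. Of 75 mitochondrial ribosomal genes, 59 were lower (median log2 fold change -0.43, camera adjusted p 5.71e-05, and adjusted p = 0.627 with an estimated correlation). Mrpl35 had 86.3 ± 19.2 CPM in WT and 40.2 ± 5.92 in the knockout, and Mrpl12 had 211 ± 52.4 and 93.0 ± 29.5. This call held with each library left out, although the mean relative change went from -0.34 to -0.20 without knockout replicate 2, and was -0.51 without both WT replicates 1 and 2. Of 76 oxidative phosphorylation genes, 53 were lower (median -0.35, camera adjusted p 0.00119, and adjusted p = 0.627 with an estimated correlation). Ndufb7 and Ndufa13, subunits of respiratory complex I, had 168 ± 39.7 and 386 ± 205 CPM in WT and 80.3 ± 16.7 and 155 ± 22.9 in the knockout. Without WT replicate 3 the adjusted p of this list was 0.0681 at a mean relative change of -0.26, against -0.25 with all libraries, and without knockout replicate 2 the mean was -0.13 (0.0445). Cytosolic ribosomal proteins were lower in 55 of 77 (median -0.29, camera adjusted p 0.0140, and adjusted p = 0.748 with an estimated correlation). Rpl15 had 23.8 ± 9.97 CPM in WT and 57.9 ± 8.67 in the knockout, and Rpl19 had 260, 69 and 58 reads in WT and 78, 84 and 100 in the knockout; both have processed pseudogenes that can share reads. Without WT replicate 1 the adjusted p of the cytosolic list was 0.286 and without knockout replicate 2 it was 0.144, with the mean relative change going from -0.26 to -0.14 in each case. By edgeR 0 members of the 3 lists passed over all genes and 0 when adjusted over the list alone, while 25, 21 and 16 were lower at an unadjusted p under 0.05. With the trends in transcript length and GC content removed, an alternative added after the data were seen, the adjusted p was 0.00395 for mitochondrial ribosomal genes, 0.417 for oxidative phosphorylation and 0.949 for the cytosolic ribosome. Without both WT replicates 1 and 2 the cytosolic list had 0.389 at a mean of -0.20. Mitochondrially encoded genes have 0 rows in the table, so they were not analysed here.

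Mitochondrial dynamics, import and quality control genes were not called (26 of 51 higher, camera adjusted p 0.602). Phb, the inner-membrane scaffold prohibitin, had 63.0 ± 20.5 CPM in WT and 28.9 ± 5.15 in the knockout. The list's median was 0.01 and its mean -0.03, of opposite sign.

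The stress lists did not pass, although 1 of them was called in other settings. Of 36 ATF4 targets of the integrated stress response 19 were higher (camera adjusted p 0.201), with Vldlr at the smallest p, and the adjusted p was 0.00270 without WT replicate 2, 0.0420 without knockout replicate 3, 0.0493 with the length and GC trends removed and 5.81e-06 without both WT replicates 1 and 2. Adjusted over the list alone 1 passed, against 0 over all genes. Of 22 genes of the endoplasmic reticulum unfolded protein response 15 were higher (0.507), among them not Pdia4, a protein disulfide isomerase with 139 ± 70.7 CPM in WT and 62.8 ± 1.45 in the knockout. Of 22 heat shock genes 13 were lower (0.166); the co-chaperone Stip1 had 189 ± 90.9 and 68.3 ± 6.19 CPM, and 2 passed when adjusted over the list alone against 0 over all genes. Of 39 NRF2 and oxidative stress genes 28 were lower (0.201), while Mgst1, a membrane glutathione transferase, had 16.6 ± 10.8 and 53.8 ± 27.0 CPM. Of 34 p53 targets 19 were lower (0.648). Apaf1, the apoptosome scaffold, is on both the p53 and the apoptosis list and had 3.36 ± 1.43 and 15.3 ± 7.20 CPM. Apoptosis regulators were split, 14 higher and 13 lower (0.728), with 2 passing when adjusted over the list alone against 0 over all genes, and a median of 0.01 beside a mean of -0.05.

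The remaining lists were not called either. Of 27 PML nuclear body and SUMO genes 15 were higher (camera adjusted p 0.648, median 0.10 and mean -0.06), and Pml passed when adjusted over the list alone, against 0 over all genes. Pias1, a SUMO ligase, had 10.8 ± 1.31 CPM in WT and 23.3 ± 3.52 in the knockout. Neuronal commitment genes were higher in 7 of 12 (0.344). Neuron genes were higher in 16 of 28 (0.667, median 0.16 and mean -0.02), with 3 passing when adjusted over the list alone against 0 over all genes; Gap43, a growth cone protein, had 350 ± 136 and 135 ± 36.8 CPM. Ventral telencephalic genes were higher in 6 of 9 (0.728), with Zfhx3 at 16.7 ± 1.66 and 10.8 ± 3.30 CPM. Oligodendrocyte lineage genes were higher in 12 of 20 (0.198). The adjusted p of that list was 0.0258 without WT replicate 2, 0.00126 without knockout replicate 1 and 0.00327 without both WT replicates 1 and 2. Interferon and antigen presentation genes were lower in 19 of 25 (0.201), with the immunoproteasome subunit Psmb10 at 32.8 ± 14.0 and 16.4 ± 1.43 CPM. Cholesterol synthesis genes were lower in 17 of 24 (0.533; 0.0241 without WT replicate 2), with Mvd at 240 ± 173 and 84.6 ± 14.4 CPM. Autophagy and lysosome genes were lower in 23 of 41 (0.648), although Ctsl, cathepsin L, had 39.5 ± 5.36 and 80.6 ± 11.9 CPM. Wnt genes were higher in 15 of 22 (0.344), with the receptor Fzd3 at 97.8 ± 28.8 and 160 ± 31.9 CPM. Immediate early genes were lower in 14 of 26 (0.912), with Etv5 at 144 ± 96.6 and 58.0 ± 11.8 CPM; camera ranked this list upward while its median was -0.05, and its adjusted p was 6.74e-05 without both WT replicates 1 and 2.

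Few markers of other cell types reached the count filter. Of 20 microglia and macrophage genes 0 reached the count filter. The most any library held over the list was 48 reads, in WT replicate 2, the shallowest library, with 21 of them from Csf1r. The list stood at 21.4 ± 20.4 CPM outside Rn45s in WT and 5.86 ± 1.81 in the knockout. The endothelial, mural and posterior (Hox) lists had 4 tested members each, the ependymal list 3 and the blood list 1, too few for camera. Summed over all members, per count outside Rn45s, the WT and knockout means differed by less than the SD in WT for the microglial, endothelial, mural, posterior and ependymal lists. For the blood list they did not. The mural, meningeal and mesenchymal list stood at 101 ± 16.3 CPM outside Rn45s in WT and 108 ± 27.7 in the knockout, the ependymal and choroid plexus list at 109 ± 98.1 and 61.8 ± 13.1, the posterior list at 55.4 ± 18.8 and 51.4 ± 18.3 and the endothelial list at 44.4 ± 19.3 and 35.6 ± 6.34. Of the 4 tested endothelial genes 3 were lower (median log2 fold change -0.47), and 1 of them passed when adjusted over the list alone, against 0 over all genes. Of the 4 tested mural genes 2 were higher and 2 lower, with 0 passing over all genes or when adjusted over the list alone, and Myl9, a myosin light chain of smooth muscle, had the smallest p (12.9 ± 10.3 against 4.69 ± 1.57 CPM). Ttr, which choroid plexus and liver both make, had 31, 167 and 13 reads in WT replicates 1, 2 and 3 and 60, 62 and 39 in the knockout libraries. The blood list stood at 64.5 ± 37.3 CPM outside Rn45s in WT and 142 ± 13.7 in the knockout, nearly all of it from Tfrc. Tfrc was the list's tested member, the transferrin receptor that dividing cells also use, at 48.6 ± 24.8 CPM in WT and 100 ± 11.8 in the knockout. Over 10 haemoglobin genes 0 reads were counted in each library, which allows up to 2.81 CPM outside Rn45s in the shallowest, WT replicate 2.

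The authors' deposited table called 363 of 12349 genes, 139 higher and 224 lower in the knockout. Of these, 330 were tested here, and all 330 had the same sign and an unadjusted p under 0.05 by edgeR. The edgeR exact test called 303 of them and DESeq2 271. In the authors' deposited table Wdfy1 had a log2 fold change of 2.97 with an adjusted p of 2.42e-09, and Pml -2.79 with 0.00302. Of the 224 genes lower in the authors' deposited table, 44 are on the hepatocyte list, and of the 139 higher, 0 are. That list was written after the values were seen, so these counts are no independent evidence of a direction.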

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

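The calls depended on the test and on single libraries; the cause was not tested. Genes higher in the knockout numbered 1 with upper quartile factors, no count filter, a non-robust fit and without the hepatocyte list. They numbered 0 with DESeq2's size factors, library totals, a minimum of 5 CPM, limma voom, an adjusted p of 0.01, glmTreat, without Rn45s, and with the length and GC trends removed. Genes lower numbered 0 in all of these but the fit with no count filter, which gave 2. The counts, higher and lower, were 93 and 221 by DESeq2, 148 and 211 by the edgeR exact test, 482 and 760 by voom with quality weights, and 91 and 51 without both WT replicates 1 and 2, where the lone WT library is assumed to vary like the knockout libraries. With 1 library left out, counts ran from 0 to 589 higher and from 0 to 937 lower, both highest without WT replicate 3, and 2 to 14 lists were called, fewest without WT replicate 3 and most without WT replicate 2. Alternatives with Rn45s, the hepatocyte list, quality weights, both WT replicates and length and GC were chosen after seeing the data. The quality weights were 1.62, 0.392 and 0.353 for WT replicates 1, 2 and 3. The weighted voom fit thus leans on WT replicate 1 and shares the limit of the fit without WT replicate 3. Library totals moved the median log2 fold change of all genes to 0.43, so list values below are relative to the mean of all tested genes.

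Camera kept the report's 13 calls with DESeq2's size factors, without Rn45s and without the hepatocyte list. Without both WT replicates 1 and 2 it called 13 lists, of which 9 were among them. It called 10 with a minimum of 5 CPM, 7 with library totals, 7 with length and GC trends removed, and 0 with an estimated correlation, and fry called 0. Of the 13 calls in the report, 2 were kept without WT replicate 3, and 0 turned in any alternative. The replicate numbers are those of the sample titles. The knockout library names are numbered 2 to 4 and the WT names 1 to 3, so the title numbers need not mark related libraries. The deviations gave no pairing throughout: same-numbered ones correlated at -0.003, 0.07 and 0.19, and not every library correlated best with its own number. The highest value of any pair, 0.19, was that of the replicates numbered 3. With 3 libraries per genotype this check cannot tell whether same-numbered libraries are related. With the replicate number as a block, 1 gene was higher, 1 lower, and 6 lists were called. The block ended the calls of the stem cell, dorsal, astrocyte, Notch, Hedgehog, BMP and sex-linked lists. Their camera adjusted p lay between 0.0519 (BMP) and 0.0806 (astrocyte).

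Lists without a call changed sign in mean relative change as follows, as ranges over single libraries left out: G2/M -0.396 to 0.203, PML bodies -0.106 to 0.034, apoptosis -0.077 to 0.117, heat shock -0.243 to 0.038, immediate early -0.408 to 0.359, integrated stress response -0.198 to 0.42, mitochondrial dynamics -0.021 to 0.087 and neuron -0.07 to 0.131. Without both WT replicates 1 and 2, neuronal commitment was at -0.203, p53 targets at 0.129, interferon at 0.273, immediate early at 0.681, and the genes Mvd at 0.033, Rpl19 at 0.031 and Ttr at 1.488. Ttr ran from -3.012 to 0.497 over single libraries left out, with the only rise without WT replicate 2. With length and GC trends removed, neuron was at -0.001, ventral telencephalic at -0.109, mitochondrial dynamics at 0.042 and apoptosis at 0.037. Neuron was at -0.001 without the hepatocyte list, ventral telencephalic at -0.051 with a minimum of 5 CPM, mitochondrial dynamics at 0 with library totals and 0.001 without Rn45s, and apoptosis at 0.027 with the replicate block. Named genes kept their direction in 734 of 738 values. Most were picked for a small p in these same libraries, so a kept direction was likely in advance and is no independent support. Depth limits genes near the filter most in WT replicate 2.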

Other observations

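Tests of a fixed number of background reads, of depth for WT replicates 1 and 2 singly, of transcript length and GC trends and of a mislabelled library, and the repeats of the thinning, were chosen after the result they bear on was seen. The hepatocyte list and the histone and small nucleolar RNA groups were also chosen from the data. Of 15 tested replication-dependent histone genes, whose RNAs mostly lack a poly(A) tail, 13 were lower, 12 of them at an unadjusted p under 0.05 by edgeR, with a median log2 fold change of -1.92. They summed to 2384, 777 and 753 CPM of the counts outside Rn45s in WT replicates 1, 2 and 3 and to 658, 428 and 516 in the knockout libraries. Of 6 tested small nucleolar RNA genes 5 were lower (median -2.88), at 2299, 1802 and 158 CPM in the WT libraries and 194, 218 and 195 in the knockout libraries, so that these rest on WT replicates 1 and 2, and WT replicate 3 lay below every knockout library.

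Within 5 Mb of Pml, 66 genes were tested and 15.2% had an unadjusted p under 0.05, against 15.9% of all tested genes.

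With 3 libraries against 3 there are 10 splits, too few for a share under 0.05. The real split gave 1 gene higher, 0 lower and 13 lists. The highest of the other 9 gave 0 genes in either direction and 12 lists. As many genes higher came from 1 of the 10 splits, as many lower from 10, and as many lists from 1.

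Hepatocyte genes were higher in the WT libraries than in the knockout libraries: all 49 tested members of the list, 3 of whose 69 genes are also on other lists, were lower in the knockout. Because the list was written after the values were seen, this count describes the list and does not test it. Fgb, with the most reads, had 289, 149 and 135 in WT and 131, 66 and 124 in the knockout, Alb had 253, 52 and 82 against 79, 48 and 62, and others such as Trf and Cp are also made in brain. WT replicates 1, 2 and 3 held 4362, 2836 and 1794 reads of the list, and the knockout libraries 1688, 1191 and 1381. WT replicates 1 and 2 had 2.584 (95% interval 2.44 to 2.74) and 1.68 (1.58 to 1.79) times the reads of the highest knockout library. These ratios argue against a fixed number of background reads in every library as the cause for WT replicates 1 and 2. WT replicate 3 had only 1.063 times (0.994 to 1.14), so for it a fixed number stays open. A single liver source remains open too, and the ratio test cannot decide it. The list's counts varied less in their ratios across libraries than those of most matched lists. Its 5.99 chi-square per degree of freedom, against a median of 7.96, lay at the 4.7 percentile of 1000 lists. That is within drawing error of the percentile of 5 set beforehand. But the genes were picked after the values were seen and all 49 tested members moved the same way, which favours a low percentile. The value of 5.99 is also more than counting error alone would give, with no molecular identifiers named to tell duplicate reads apart. The genotype was not tested as a source and stays open, and the labels name no liver sample.

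Oxidative phosphorylation and ribosomal genes have short transcripts with GC-rich ends, with median lengths of 937 and 943 bases against 3280 for all tested genes, and log2 fold changes correlated across genes with length (Spearman 0.258) and with end GC (-0.426), genes not being independent replicates. With both trends removed, the mean relative change of mitochondrial ribosomal genes went from -0.339 (SD over members 0.484) to -0.229 (0.522). Camera with the preset correlation still called that list (adjusted p 0.00395). With an estimated correlation camera did not call it even before the trends were removed (adjusted p 0.627). Whether the trends are the whole cause there therefore stays open. The mean relative change of oxidative phosphorylation went from -0.252 (0.578) to -0.022 (0.510). For the cytosolic ribosome it went from -0.257 (0.603) to -0.005 (0.590). Both calls ended because the means moved to near 0. For these 2 lists the trends are a candidate explanation. Removing the trends also ended the calls of 5 lists that were higher, whose means became smaller without reaching 0: stem cell from 0.393 (SD over members 0.688) to 0.236 (0.762), dorsal from 0.468 (0.403) to 0.392 (0.262), Hedgehog from 0.515 (0.697) to 0.373 (0.719), BMP from 0.423 (0.477) to 0.214 (0.547) and sex-linked from 0.663 (0.378) to 0.362 (0.423). What part of these the trends explain stays open. Whether the trends themselves come from genotype, library preparation or RNA quality was not tested.

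WT replicates 1 and 2 stood apart from WT replicate 3, and whether they form one set depends on the measure. By root mean square log2 difference over the 500 most different genes, at full depth without Rn45s, WT replicate 1 was nearer to WT replicate 3 (2.5) than to WT replicate 2 (3.509). By chi-square per degree of freedom over the counts of all tested genes, Rn45s included, which the abundant genes weigh on most and which grows with depth, WT replicates 1 and 2 were nearer to each other (18.3) than to WT replicate 3 (68.5 and 59.3). Depth as the whole cause is argued against for WT replicate 2. With every library thinned to 1068340 counts outside Rn45s, its distance to WT replicate 3 was 2.302 times the mean distance among knockout libraries (2.279 to 2.359 over 20 thinnings). For WT replicate 1 depth stays open: the ratio was 1.498 (1.437 to 1.504), around the bound of 1.5 set beforehand for the mean of both, against 1.423 for the farthest knockout library. The mean of both, 1.9, was above that bound because of WT replicate 2. A mislabelled knockout library is argued against for WT replicate 3, which had Pml at 13.91 CPM outside Rn45s (95% interval 10.1 to 18.7), near WT replicate 1 at 14.0, against at most 5.41 (3.43 to 8.12) in the knockout libraries. Fewer distinct transcripts in WT replicates 1 and 2 stay open. At equal depth WT replicates 1, 2 and 3 detected 12682, 12326 and 12719 genes. Knockout replicates 1, 2 and 3 detected 13023, 13154 and 13038. WT replicate 1 thus lay near WT replicate 3, below every knockout library, and WT replicate 2 was lowest. The gap between WT replicates 1 and 2 and the other libraries was above 0 in 20 of 20 thinnings but as small as 6 genes. Differences between cultures of the same genotype were not tested and stay open too.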
